A study of Rattus norvegicus with 50 samples.

How the data were processed

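Tissue from the medial prefrontal cortex of Wistar rats was sampled at 5 postnatal ages in wild-type animals and in animals lacking the serotonin transporter, with 5 libraries per genotype and age. Per the labels' protocols, ribosomal RNA was removed from total RNA, the RNA was fragmented, libraries were amplified by 10 cycles of PCR, and 50 bp single-end reads were sequenced on an Illumina HiSeq 2000 to about 29000000 reads per sample. No strand protocol is stated, so reads from overlapping genes on opposite strands may be counted together. The labels' extraction protocol gives gsnap as the aligner to the rn4 rat assembly, while the submitters' processing notes list BWA 0.6.1, bedtools and Cufflinks with rn4, and which aligner made the tables is not settled here. The gene annotation release is not given in the sources used here.

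The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library), given by the authors in one table of knockout and one of wild-type libraries with the same 29516 Ensembl identifiers. Cufflinks, named in the processing notes, estimates FPKM, and the basis of its scaling in these tables is not given in the sources used here. Every column was matched to a sample by the genotype, age and numbers of its title, and 0 columns were left unmatched. The first title number is particular to a genotype and age, 3 of them occur in each group, and the labels do not say what it stands for. No replicate number occurs in more than 1 group, so none pairs samples.

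The files do not pair identifiers with gene names. The reference table of the assembly GRCr8 used here lists 0 Ensembl rat gene identifiers, so none could match and no symbols, functions or coordinates are given. This says nothing about whether the genes are in that assembly. The serotonin transporter gene, and the lists of cell type, synaptic, myelin, serotonin and other genes fixed before the data were examined, were for that reason not analysed here, nor were set tests on them.

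Absolute depth is unknown. In rows seen in at least 3 and at most 25 libraries, values were compared between libraries to find what 1 read was worth in each, which gives depth as a ratio. This used 4242 rows and values of at least 0.001 FPKM. In the median pair of libraries 94.0% of the ratios lay within 0.02 log2 units of a ratio of small whole numbers. Between 17833 and 20161 rows per library were above 0. An exact 0 can be a failed estimate: of 4943 rows with a median of at least 10 FPKM, 35 were at exactly 0 in some library. Such a row is described here as listed at 0.

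Each library was divided by its median ratio to the geometric mean of all libraries (factors 0.829 to 1.21), and values were tested as log2(FPKM + 0.5). Fold changes on this scale understate the change of low genes. Genes with a mean of at least 0.5 FPKM over the 50 libraries were kept, 14779 in all. A linear model with 10 groups was fitted with limma 3.58.1 in R 4.3.3, with 40 residual degrees of freedom and moderated statistics with a trend and robust variance. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the genes of one comparison. The comparisons were knockout against wild-type at each age and on average over the ages, the dependence of that difference on age (a moderated F test), consecutive ages and days 8 to 70 within each genotype, and the difference of each consecutive change between genotypes. Maturation scores used 200 genes per direction, chosen by moderated statistic in wild-type libraries of other ages, and exact permutation tests. The intervals hold the shifts that the exact test does not reject at the 95% level. With 5 libraries against 5 the smallest exact p is 0.00794. Depth and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

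The genes to be named were to be the 12 with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 FPKM and a symbol, and, at a single age, without overlap between the genotypes. Without symbols that condition was dropped, and at most 2 identifiers per direction are given for a comparison. The rule was applied to day 8, day 14, the average over ages and the wild-type change from day 8 to 70.

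The test was checked on simulated FPKM built from the group means and residual spread of the real genes, with 200 genes changed 1.2, 1.5, 2 or 3-fold. For day 8 it ran on 14682 genes and called 129, of which 10 had not been changed. With no gene changed it called 0. The noise was drawn separately for each gene and library, so spread that genes share within a library was not simulated. The simulated shares and false calls may therefore not hold for the real libraries. For the average over ages it found 70% of the genes changed 1.2-fold at all ages. For the difference of the change from day 8 to 14 it found 2% of those changed 1.2-fold and 80% of those changed 2-fold.

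The alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter or a mean of at least 2 FPKM, the values as deposited, quantile normalization, a fit of only the groups compared, array weights, the first title number as a random effect or as a unit for averaging, scores of 50 or 500 genes per direction or from knockout libraries, and leaving out each library in turn. Others were added after seeing the data: leaving out 4 libraries that stood apart on a residual component, and total FPKM or relative depth as a covariate. No gene sequences, coordinates or individual reads were used here.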

Results

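Gene expression was measured by RNA sequencing of ribosomal-RNA-depleted total RNA from the medial prefrontal cortex of Wistar rats. One genotype was wild-type, and the other lacked the serotonin transporter, the membrane protein that takes serotonin back up from the extracellular space. The animals were taken at postnatal days 8, 14, 21, 35 and 70, which run from the second week of life to young adulthood. Each of the 10 combinations of genotype and age held 5 libraries, 50 in all, and each library had a value in FPKM for 29516 Ensembl gene identifiers. The labels do not say whether the 5 libraries of a group came from 5 rats, so the p-values measure the spread between these libraries. Read depth was recovered only as a ratio between libraries. It lay between 0.521 and 1.42 times that of the median library in knockout rats and between 0.397 and 1.35 times in wild-type rats. Total FPKM per library ran from 330440 to 2141919, and the 50 most abundant rows held 46.6% to 81.5% of it. No pair of libraries was identical, and correlations between libraries of one group ran from 0.881 to 0.982 on the log2 scale. The tables gave identifiers without symbols, so genes are named by identifier, and the serotonin transporter gene itself was not analysed here.

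The first question was how the wild-type cortex changed with age. Between days 8 and 70, 4107 genes rose and 4045 fell out of 14779 tested, and 1889 of these changed more than 2-fold. The balance of directions depended on the scaling. With the values as deposited, which moved the median log2 change of all genes by -0.14 in wild-type and -0.10 in knockout rats, 3009 genes rose and 5105 fell over this span in wild-type rats. With quantile normalization 3998 rose and 4064 fell. ENSRNOG00000015763 had the largest rise, from 0.223 ± 0.164 FPKM at day 8 to 1.01 ± 0.257 at day 14, 9.68 ± 0.887 at day 21, 28.9 ± 5.26 at day 35 and 29.2 ± 2.91 at day 70 (mean ± SD, n = 5 at each age). ENSRNOG00000013484 followed a like course, from 0.452 ± 0.20 FPKM at day 8 to 14.2 ± 2.93 at day 21 and 27.5 ± 1.74 at day 70. In the opposite direction, ENSRNOG00000005797 fell from 37.0 ± 4.69 FPKM at day 8 to 13.3 ± 1.64 at day 14, 1.94 ± 0.450 at day 21 and 0.924 ± 0.191 at day 70. The log2 changes from day 8 to 70 were 5.39 ± 0.19 (SE) for the first gene, 4.90 ± 0.13 for the second and -4.72 ± 0.18 for the third, with limma adjusted p of 2.51e-26, 4.58e-30 and 4.13e-25. The largest fitted fall, of ENSRNOG00000034416 (log2 change -5.05 ± 1.63 SE, limma adjusted p = 0.00788), rested on libraries listed at 0. Its 5 wild-type values lay between 87.6 and 155 FPKM at day 8, between 0 and 0.781 at day 14, between 32.4 and 47.2 at day 21 and between 0 and 37.5 at day 70.

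Most of this change came early in both genotypes. In wild-type rats 2570 genes rose and 2411 fell between days 8 and 14, with a median absolute log2 change of 0.48 (2101 and 2366 with the values as deposited). Another 1520 rose and 1495 fell between days 14 and 21, against 835 and 1976 as deposited and 1280 and 1522 with quantile normalization. The interval from day 21 to 35 held 272 rising and 299 falling genes (125 and 231 as deposited), and the interval from day 35 to 70 held 14 rising and 36 falling. Knockout rats gave 2763 rising and 2556 falling genes in the first interval, 1578 and 1490 in the second, 286 and 378 in the third, and 21 and 24 in the last. As deposited, the knockout values gave 2157 rising and 2618 falling genes in the first interval, 1093 and 1433 in the second, 240 and 147 in the third, and 3 and 15 in the last. With quantile normalization they gave 2511 and 2656, 1447 and 1545, 256 and 340, and 24 and 20. The majority direction of near-even counts turned with the scaling. As deposited it turned in the first and second interval of both genotypes and the third of knockout rats, and with quantile normalization in the second interval of both genotypes and the first and last of knockout rats. The later counts moved with the choice of test. When only the groups compared were fitted, the wild-type counts were 1838 for days 14 to 21, 174 for days 21 to 35 and 7 for days 35 to 70, and the knockout counts for the last pair of intervals were 288 and 4. Averaging libraries by first title number gave 2000, 205 and 8 in wild-type and 225 and 5 in knockout rats for the same intervals, while array weights gave 1628 and 187 in wild-type and 1222 and 205 in knockout rats for the last pair and 4788 in knockout rats for days 14 to 21. Leaving out knockout library 18-1 of day 21 gave 405 genes in place of 664 for days 21 to 35, leaving out wild-type library 11-4 of day 35 gave 364 in place of 571, and leaving out knockout library 5-3 of day 70 gave 29 in place of 45 for days 35 to 70.

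**Figure D1:**
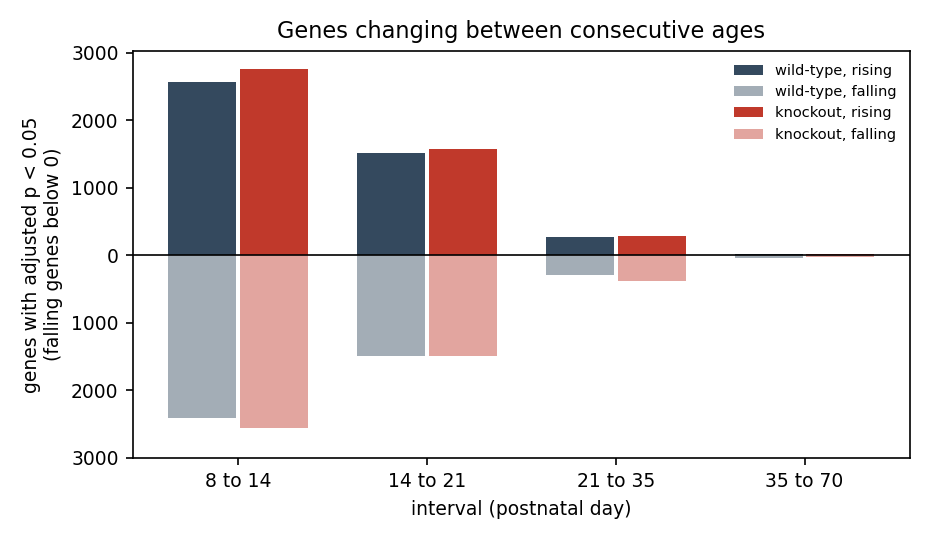
Number of genes with a limma adjusted p under 0.05 (vertical axis, rising genes above 0 and falling genes below 0) for each interval between consecutive ages (horizontal axis, postnatal days), for wild-type (blue) and knockout (red) rats with 5 libraries per group. The wild-type bars go from 2570 rising and 2411 falling genes in the first interval to 14 and 36 in the last. The values are rescaled, and the majority direction of near-even pairs of bars turns with other scalings (as deposited, 240 and 147 in place of 286 and 378 for knockout rats at days 21 to 35).

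Genes called in both genotypes changed in the same direction, with few exceptions. Of the 2570 genes that rose in wild-type rats between days 8 and 14, 1969 also rose in knockout rats and 1 fell, where independent lists of these lengths would share 481. Of the 2411 that fell, 1695 also fell and 0 rose, against 417 for independent lists. Between days 14 and 21, 1178 of 1520 rising genes and 1140 of 1495 falling genes passed the same way in knockout rats, and 0 passed the opposite way. For days 21 to 35 the shared genes were 123 of 272 and 168 of 299, and for days 35 to 70 they were 7 of 14 and 12 of 36, with 0 passing the opposite way in either interval. Over the whole span from day 8 to 70, 3597 of 4107 rising and 3500 of 4045 falling genes were shared, with 1 in each direction going the other way. Across genes, which are not independent replicates, the changes from day 8 to 70 in the 2 genotypes had a Pearson r of 0.921 and a Spearman rho of 0.896. For the consecutive intervals, in order of age, Pearson's r was 0.712, 0.740, 0.249 and 0.346, and Spearman's rho was 0.724, 0.796, 0.340 and 0.418. No library entered the fitted changes of both genotypes, but the spread of each gene was estimated from all 50 libraries. A gene with a small spread passes more readily in both genotypes, so the numbers for independent lists are low benchmarks.

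Genes of one interval were followed into the next, where most did not pass. To keep the libraries of the 2 intervals separate, genes were taken from the wild-type change and followed in knockout rats. The spread of each gene still came from all libraries, so the numbers for independent lists are low benchmarks here too. Of the 2570 genes that rose between days 8 and 14 in wild-type rats, 1002 rose, 51 fell and 1517 did not pass between days 14 and 21 in knockout rats, where independent lists would share 274 rising and 259 falling genes. Of the 2411 that fell, 901 fell further, 38 rose and 1472 did not pass, against 243 and 257 for independent lists. Of the 1520 genes that rose between days 14 and 21, 158 rose, 19 fell and 1343 did not pass between days 21 and 35 (29.4 and 38.9 for independent lists). Of the 1495 that fell, 175 fell, 6 rose and 1314 did not pass (38.2 and 28.9). Of the 272 that rose between days 21 and 35, 11 rose, 0 fell and 261 did not pass between days 35 and 70, and of the 299 that fell, 15 fell, 0 rose and 284 did not pass.

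The main question of the design was whether loss of the transporter changed expression at each age. At day 8, 15 genes were higher and 21 lower in knockout than in wild-type rats, with log2 differences from -1.05 to 1.22. ENSRNOG00000002916 was lower, at 1.28 ± 0.187 FPKM in knockout and 2.97 ± 0.731 in wild-type rats (SD, n = 5 each). Its log2 difference was -0.94 ± 0.12 (SE) with a limma adjusted p of 1.35e-05. ENSRNOG00000017679 was also lower, at 1.80 ± 0.590 against 3.50 ± 0.979 FPKM (log2 difference -0.81 ± 0.15 SE, limma adjusted p = 0.00509). Among the genes that were higher, ENSRNOG00000031222 stood at 2.34 ± 0.233 against 1.43 ± 0.0987 FPKM (log2 difference 0.55 ± 0.12 SE, limma adjusted p = 0.0360) and ENSRNOG00000014550 at 12.0 ± 1.51 against 8.90 ± 0.508 FPKM (log2 difference 0.41 ± 0.09 SE, limma adjusted p = 0.0367). In these 4 genes every knockout library lay beyond every wild-type library, as the rule for naming required. The rule passed over the largest rise (log2 difference 1.22) and the largest fall (-1.05). In these, 3 and 4 of the 5 knockout libraries lay beyond all wild-type libraries. An absence of overlap held for 2 of the 15 higher and 11 of the 21 lower genes. Among all 14779 genes it held for 45 in the first direction and 81 in the second, where chance gives 0.794% of genes, or 117.

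The day 8 count of 36 rested on single libraries and on the test. It was 23 with the first title number as a random effect and 1 with libraries averaged by that number, but 77 with no filter, 222 with array weights and 92 without 4 libraries that stood apart, an alternative chosen after seeing the data. The 15 higher genes lay a median of 1.18, 0.95 and 1.00 log2 units above the wild-type mean in knockout libraries 29-4, 29-5 and 30-1, but 0.33 in library 30-5 and 0.11 in library 28-1. Without knockout library 29-4 only 1 gene passed, without 30-1 10 genes and without 29-5 15 genes. Without wild-type library 25-2 or 26-1 6 genes passed, and without 27-4 21 genes. Leaving out knockout library 30-5 or 28-1 instead raised the count to 71 and 162. No gene passed when the 10 libraries of day 8 were fitted alone, and 1377 genes had an unadjusted p under 0.05 in the fit of all groups. That is more than a share of 0.05 of the 14779 genes, the average under chance alone, but genes are not independent. With the values as deposited 2 genes were higher and 17 lower, and with quantile normalization 19 were higher and 19 lower. ENSRNOG00000002916 lost its call in 1 of 23 alternatives, the fit of day 8 alone (limma adjusted p = 0.275). The call of ENSRNOG00000031222 and that of ENSRNOG00000014550 were each lost in 13 of the 23, and that of ENSRNOG00000017679 in 4. Of 100 splits of the 10 libraries, the real one included, 8 gave 36 genes or more. The 2 genotypes came in separate tables, and a factor particular to one gene in one table would not be removed by rescaling.

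At later ages few or no genes differed. At day 14 the one gene that passed was ENSRNOG00000002916, at 2.64 ± 0.404 FPKM in knockout and 4.66 ± 0.664 in wild-type rats (SD, n = 5 each; log2 difference -0.72 ± 0.12 SE, limma adjusted p = 0.00690). This call was lost without knockout library 23-3 or 24-1, without wild-type library 19-1, in the fit of day 14 alone and with libraries averaged by title number, with limma adjusted p up to 0.474. The count was 3 without knockout library 24-2, 2 without wild-type library 21-3, 2 with the values as deposited and 3 with array weights. No gene passed at days 21, 35 or 70 by limma, where 436, 377 and 354 genes had an unadjusted p under 0.05. Each of these counts is below a share of 0.05 of the 14779 genes, the average under chance alone. In the fit of day 21 alone 1 gene passed. In simulated data with 200 changed genes at day 8, the same test found 12% of those changed 1.2-fold, 54% of those changed 1.5-fold, 82% of those changed 2-fold and 90% of those changed 3-fold. The simulated folds were of FPKM + 0.5, which for low genes means larger changes of FPKM. The simulated noise was independent between genes, so these shares may not hold for the real libraries. Other splits of the real libraries of day 8 gave up to 90 genes.

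Averaged over the 5 ages, 1 gene was higher and 4 were lower in knockout rats. ENSRNOG00000020446 was higher by 0.34 ± 0.06 log2 units (SE; limma adjusted p = 0.00769), with 9.08 ± 1.63 against 6.40 ± 0.964 FPKM at day 8 and 4.92 ± 0.756 against 5.13 ± 1.17 at day 70 (SD, n = 5 each). With the values as deposited its call was lost, and 0 genes were higher and 5 lower. ENSRNOG00000007722 was lower by a log2 difference of -0.39 ± 0.06 (SE; limma adjusted p = 0.00143), and its knockout mean lay below the wild-type mean at every age, with 5.06 ± 1.70 against 7.95 ± 1.07 FPKM at day 8 and 1.84 ± 0.449 against 2.20 ± 0.254 at day 70. ENSRNOG00000002916 was also among the 4, with a mean log2 difference of -0.33 ± 0.05 (SE; limma adjusted p = 0.00143). When libraries that share the first number of their title were averaged, 1 gene passed, without knockout library 28-1 of day 8, 9 passed, and with array weights 12 passed. The 2 genotypes came in separate tables. A factor particular to one gene in one table would not be removed by rescaling and could give a difference on average over ages.

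The dependence of the genotype difference on age was tested directly. ENSRNOG00000002916 alone passed this test (limma adjusted p = 0.000315), and 470 genes had an unadjusted p under 0.05. Its knockout level rose from 1.28 ± 0.187 FPKM at day 8 to 3.49 ± 0.244 at day 21, 4.28 ± 0.654 at day 35 and 4.87 ± 0.336 at day 70, while its wild-type level was 4.37 ± 0.635 at day 21, 4.23 ± 0.449 at day 35 and 4.07 ± 0.967 at day 70 (SD, n = 5 each). The test gave 13 genes without knockout library 28-1 of day 8, 7 without 30-5 and 2 without wild-type library 27-2, 0 with libraries averaged by title number, 2 with no filter and 33 with array weights. No gene had a change between consecutive ages that differed between genotypes by limma. The genes with an unadjusted p under 0.05 numbered 924 for days 8 to 14, 183 for days 14 to 21, 492 for days 21 to 35 and 265 for days 35 to 70. Of these counts and the 470 above, only 924 exceeded a share of 0.05 of the 14779 genes, the average under chance alone. Without knockout library 28-1 of day 8, 16 genes passed for days 8 to 14, and without 30-5 4 did. Array weights gave 25 for that interval, and no filter gave 2.

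**Figure D2:**
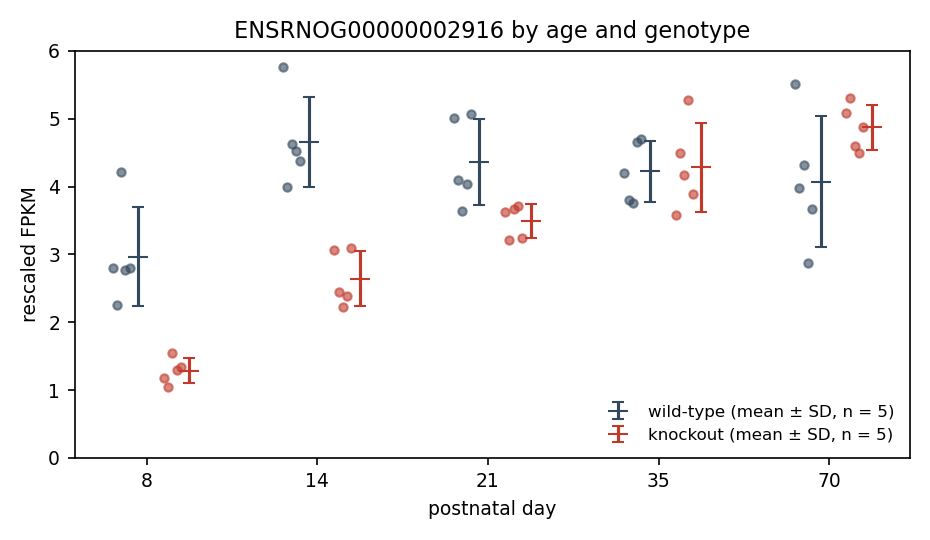
Rescaled FPKM (vertical axis) of ENSRNOG00000002916 in each library at each postnatal day (horizontal axis), with wild-type rats in blue and knockout rats in red. Points are libraries, and the bars give mean ± SD of 5 libraries. At day 8 the knockout mean was 1.28 and the wild-type mean 2.97, and at day 35 they were 4.28 and 4.23.

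A maturation score asked whether knockout cortex ran ahead of or behind wild-type cortex. For each age it was the mean log2 value of 200 genes that rose minus that of 200 that fell between 2 other ages in wild-type rats. The genes were those with the largest moderated statistic in each direction, and the spread in that statistic came from all 50 libraries. At day 8 the knockout score was higher by 0.02 log2 units, with an exact 95% interval from -0.14 to 0.16 (exact permutation p = 0.722, two-sided, n = 5 each). The differences were -0.06 at day 14 (-0.34 to 0.32, exact permutation p = 0.683), -0.02 at day 21 (-0.10 to 0.06, p = 0.619), -0.03 at day 35 (-0.09 to 0.03, p = 0.389) and -0.03 at day 70 (-0.08 to 0.01, p = 0.0952). The smallest adjusted p over the 5 ages was 0.476. For scale, the wild-type score of the day 8 gene set rose by 1.11 from day 8 to 14, so the interval at day 8 ran from -12.4% to 14.7% of that step. Against the wild-type step to the next age it ran from -23.5% to 22.6% at day 14, from -12.9% to 6.97% at day 21 and from -16.5% to 6.15% at day 35. At day 70 the difference was -24.7% of the wild-type step from day 35 to 70, which was 0.14, with an interval from -56.9% to 3.97%. A lag as large as its lower bound was not excluded. Each of these steps began or ended with wild-type libraries that had also chosen the genes. Selection may thus have shrunk the steps used at days 8 and 70 and widened the others, so the percentages are rough. At day 14 the knockout libraries were spread widely, from 0.30 to 1.09 (SD 0.35), while the wild-type libraries lay between 0.57 and 0.70 (SD 0.05).

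**Figure D3:**
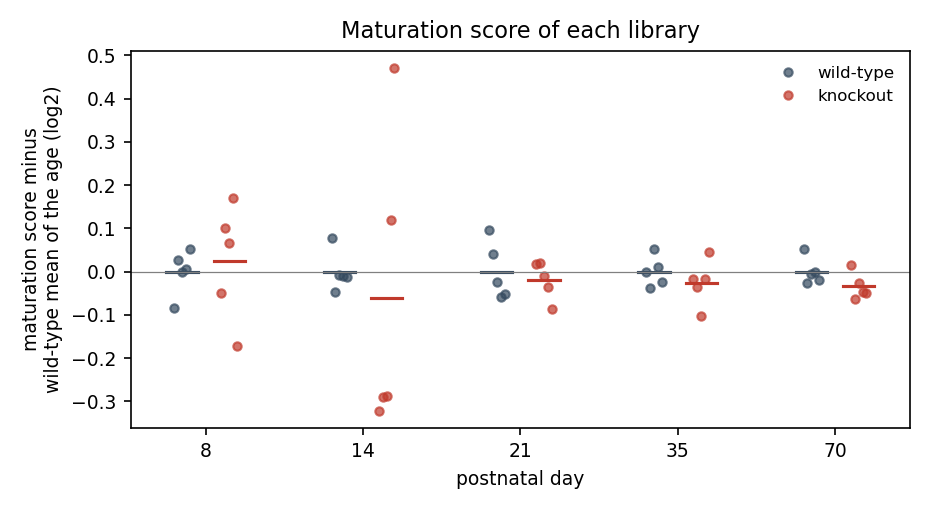
Maturation score of each library minus the wild-type mean of its age (vertical axis, log2 units) at each postnatal day (horizontal axis), with wild-type libraries in blue and knockout libraries in red, 5 of each per age. Horizontal bars are group means. The knockout libraries of day 14 have an SD of 0.35, against 0.05 in wild-type libraries of that age.

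Genotype differences at one age were compared with those at another. Over the 10 pairs of ages, Pearson's r across genes ran from -0.25 to 0.23, with a mean of -0.02. Of 100 relabellings of genotype within ages, 72 gave a mean at least this far from 0. Genes are not independent replicates, and no libraries were shared between ages.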

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

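The tests of a shared title number and of equally shallow libraries for the 4 libraries below, of the row at 0, of the depth of the day 8 groups, of total FPKM and of the lower genes of day 8 were chosen after the results were seen, as were the alternatives with a covariate or without the 4 libraries.

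The genotype difference of ENSRNOG00000002916 changed with age (limma adjusted p of the dependence on age = 0.000315). Its knockout mean was below the wild-type mean by a log2 difference of -0.94 at day 8 and -0.72 at day 14, and the FPKM means were 4.28 and 4.23 at day 35. Of 100 regroupings of genotype within ages, the real one included, 6 gave 1 or more genes with such a dependence and the highest other gave 8, so chance is not excluded for the count of 1.

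Single libraries far from the other 4 of their group were looked for in 14 quantities over 140 groups, and 17 were found. The nominal rate of such flags is about 1 group in 20. It may not hold for a component drawn from the residuals themselves or for a row often listed at 0. The count of 17 therefore cannot be set against chance. The second component of the residuals, which held 16.4% of their variance, set apart knockout library 30-5 of day 8 (score 0.459), knockout 7-3 of day 35 (0.409), wild-type 21-3 of day 14 (0.410) and wild-type 16-2 of day 21 (0.389), with all other libraries at 0.129 or lower. Wild-type library 11-1 of day 35 was far from its group at 0.0877. Among single genes, ENSRNOG00000002916 stood at 4.21 FPKM in wild-type library 26-1 of day 8 against at most 2.81 in the others. ENSRNOG00000007722 stood at 8.07 FPKM in knockout library 30-5 of day 8 against at most 4.57. ENSRNOG00000020446 stood at 5.48 FPKM in wild-type 8-4 of day 35 and 7.15 in wild-type 2-2 of day 70, and ENSRNOG00000031222 at 1.26 FPKM in wild-type 27-2 of day 8, below the others. ENSRNOG00000005797 stood at 3.87 FPKM in knockout 17-2 of day 21 and ENSRNOG00000015763 at 36.1 FPKM in knockout 9-5 of day 35. ENSRNOG00000034416, a row often listed at 0, stood at 51.7 FPKM in knockout 17-2 of day 21, 37.4 in knockout 7-2 of day 35, 1.23 in knockout 6-2 of day 70, 155 in wild-type 27-4 of day 8 and 0.781 in wild-type 19-1 of day 14.

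The 4 libraries apart came from 4 groups of both genotypes. Their relative depth, 0.397 to 0.801, was lower on average than that of the other 46 (permutation p = 0.00634, two-sided). This met the criterion set in advance for depth, so a part played by depth stays open. Low depth as the whole cause is argued against by 8 other libraries that were shallower than the deepest of the 4, 6 of them shallower than 3 of the 4, and had component scores of at most 0.0681. A source shared by libraries with the same first title number is argued against for the knockout libraries among the 4 only. With these, 2 other libraries share a number, and 0 of them lay beyond the range of the remaining ones. Residual scores balance within a group, so a high score lowers those of its group mates. The scores of the 2 were -0.08 at day 8 and -0.12 at day 35. The other group mates ran from -0.184 to -0.0718 and from -0.151 to -0.0248. No other library shares a number with the wild-type libraries among the 4, so for them this source was not tested. What else sets the 4 apart stays open, and no biological explanation was tested. Without the 4, 92 genes passed at day 8, of which 32 were among the 36.

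The 15 genes higher in knockout rats at day 8 could reflect a difference in the tissue or cells sampled, in total FPKM or in depth. In the 40 libraries of other ages their mean pairwise correlation was 0.00209, at percentile 48.3 of 10000 random lists matched on expression, but 7 of the 15 averaged below 2 FPKM there (median 2.06, against 3.61 in knockout rats at day 8), where co-variation would be hard to see. The bound set in advance, a percentile that is not in the upper tail, therefore excluded nothing. The 21 lower genes had a mean pairwise correlation of 0.124 in those libraries, at percentile 99.9 of their own matched lists, as a difference in tissue or cells would give and as shared regulation also could, so this explanation stays open. With log2 total FPKM as a covariate 93.3% of the 15 genes (14) kept a limma adjusted p under 0.05 and their median log2 difference went from 0.68 to 0.67, which argues against total FPKM as the whole cause. Of all 36 calls 32 held, and the 4 lost reached an adjusted p of at most 0.0534, with a median absolute log2 difference of 0.58 before and after and a median SE of 0.137 and 0.139. Relative depth at day 8 averaged 0.964 ± 0.244 in knockout and 1.01 ± 0.0866 in wild-type libraries (SD, n = 5 each, exact permutation p = 0.571), and 34 of the 36 calls held with depth as a covariate. An effect of genotype stays open, but 8 of 100 splits gave 36 or more genes and the highest gave 90, so chance is not excluded. Why some splits of the day 8 libraries gave more genes than the genotypes was not tested.

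The row with the highest mean FPKM was at exactly 0 in 10 libraries, 5 of each genotype, and between 22940 and 366500 FPKM in the other 40. The next 10 rows had a mean log2 FPKM of 15.8 in those 10 libraries and 14.2 in the other 40 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). A failed estimate in libraries rich in abundant rows may account for the zeros, and no biological explanation was tested.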

How the results depend on the processing

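The alternatives with a covariate or without the 4 libraries that stood apart were chosen after seeing the data. Counts are of genes passing. With array weights, 222 genes differed between genotypes at day 8, 3 at day 14 and 12 on average, 33 depended on age, and 25 changed differently from day 8 to 14. The weights also gave 4788 genes for days 14 to 21 in knockout rats, 1222 (knockout) and 1628 (wild-type) for days 21 to 35, and 205 and 187 for days 35 to 70. In fits of only the groups compared, the genotype counts were 0 at days 8 and 14 and 1 at day 21. Those fits gave 1838 for days 14 to 21 in wild-type rats, 288 (knockout) and 174 (wild-type) for days 21 to 35, and 4 and 7 for days 35 to 70. With libraries averaged by first title number, which leaves fewer samples, the counts were 1 at day 8, 0 at day 14, 1 on average and 0 for age dependence. That averaging gave 2000 for days 14 to 21 in wild-type rats, 225 (knockout) and 205 (wild-type) for days 21 to 35, and 5 and 8 for days 35 to 70. With the title number as a random effect (correlation 0.0706) the day 8 count was 23. Values as deposited gave 19 at day 8 and 2 at day 14, 387 (knockout) and 356 (wild-type) for days 21 to 35, and 18 and 29 for days 35 to 70. With no filter 77 genes passed at day 8, 2 depended on age, 2 changed differently from day 8 to 14, and 68 changed from day 35 to 70 in knockout rats. Without the 4 libraries 92 passed at day 8 and 4 at day 14, 6 depended on age, 3 changed differently from day 8 to 14, and 79 (knockout) and 89 (wild-type) changed from day 35 to 70. Total FPKM as a covariate gave 2 at day 14, and relative depth as a covariate gave 86 for days 35 to 70 in knockout rats. The cause of these shifts was not tested. The averaged and reduced fits also had fewer samples, and what this did to the counts was not tested.

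Leaving out 1 library at a time gave 1 to 162 genes at day 8, 0 to 3 at day 14 and 5 to 9 on average. It gave 1 to 13 for age dependence and 0 to 16 for a change from day 8 to 14 that differed between genotypes. It gave 405 to 656 (knockout) and 364 to 638 (wild-type) for days 21 to 35 and 29 to 64 for days 35 to 70 in knockout rats. In the other comparisons every such count stayed within 1.5 times. The 267 other values stayed within 1.5 times or on their side of the threshold, among them the counts for days 8 to 14 and days 8 to 70 in both genotypes, the zeros at days 35 and 70, and the 5 maturation score differences, none of which passed its test. Named genes kept their sign in every alternative, and 134 of 1244 gene-by-setting values lost the call. All the lost calls were in genotype comparisons. Each gene chosen at day 8 lost its call in 1 to 16 of its 22 or 23 alternatives. No gene chosen for the change from day 8 to 70 lost its call. Alternatives that need gene symbols (gene lists, the transporter gene, and scores without genes of cell type lists) were not run. No paired analysis was possible because no replicate number occurs in more than 1 group. Absolute depth is unknown, so no counting error is given for any value.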

Other observations

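The tests of the persistence of the day 8 differences, of a uniform lag and of title numbers were chosen after the results were seen.

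The 36 genes that differed at day 8 had a mean signed log2 difference of 0.63 there, in the direction of the day 8 call, a value raised by their selection. The same mean was 0.06 at day 14 (exact 95% interval -0.00472 to 0.13, exact permutation p = 0.0635), 0.00 at day 21 (p = 0.905), 0.06 at day 35 (p = 0.254) and 0.01 at day 70 (p = 0.810), with 5 libraries per group and exact permutation tests, two-sided. Each interval excluded a persistence at the day 8 size, with upper bounds of 0.13, 0.05, 0.18 and 0.08. Of the 36 genes, 20 had the day 8 direction at day 14, 15 at day 21, 28 at day 35 and 16 at day 70. These intervals do not exclude a smaller persistence. Without ENSRNOG00000002916 the mean at day 14 was 0.04 (exact permutation p = 0.183).

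A slower maturation of knockout cortex was a hypothesis for the day 8 differences. Of the 21 lower genes 8 rose from day 14 to 35 in wild-type rats, and of the 15 higher genes 4 did (Fisher's exact p = 0.721, two-sided). The odds ratio of 1.67 had a 95% interval from 0.330 to 9.74, which leaves both directions open, so the bound set in advance, a p of 0.05 or more, excluded nothing. A uniform lag of the cortex larger than -12.4% of the step to day 14, the lower bound of the day 8 maturation score, is argued against by that score. The 32 genes that differed in the direction of a lag lay behind by a median of 60.1% of their own change from day 8 to 14 (mean of both genotypes), taken from the lower 95% bound of each difference, with a first quartile of 27.1%. These sizes were largely set by the selection of the genes. No called gene fell by less than 0.30 or rose by less than 0.41 log2 units, against a median absolute step of 0.71. The sizes therefore cannot tell whether a smaller uniform lag played a part. Of the 36 genes, 4 differed in the opposite direction. A delay limited to some genes stays open: against the wild-type change from day 8 to 14, 19 of the 21 lower and 9 of the 15 higher genes differed in the direction of a lag, as did 46.9% of all genes, which are not independent replicates. The difference and the change shared the wild-type libraries of day 8, whose noise moves both the same way, against a lag. The 46.9% is therefore not a neutral benchmark.

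The maturation scores of knockout libraries of day 14 were 0.74 and 1.09 for libraries 24-1 and 24-2, which share the first title number, 0.30 and 0.33 for libraries 22-1 and 22-3, which share another, and 0.33 for library 23-3. Over all groups, the 21 pairs that share a number differed by 0.0689 on average, against 0.0964 with numbers shuffled within groups (permutation p = 0.0600, one-sided), and without day 14 the p was 0.285. Whether the number marks a source of spread cannot be told apart from chance with so few pairs.

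The first component of the residuals held 27.3% of their variance and followed log2 total FPKM across the 50 libraries (Pearson r = 0.857, Spearman rho = 0.842, permutation p = 1e-05 for each, the smallest that 100000 permutations can give, and r = 0.848 without the 2 libraries farthest from the median).

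Chance in how single libraries fell into groups was argued against for each change with age. In each of the 10 such comparisons 1 of 100 splits, the real one, gave as many genes. The real counts and the highest others were 4981 and 2575 for days 8 to 14, 3015 and 1611 for days 14 to 21, 571 and 137 for days 21 to 35, 50 and 16 for days 35 to 70, and 8152 and 5127 for days 8 to 70 in wild-type rats. In knockout rats they were 5319 and 2833, 3068 and 1390, 664 and 46, 45 and 5, and 8529 and 5665. The same was found for the 5 genes that differed on average over ages (1 of 100, highest other 1), the smallest share that 100 splits can give. All these splits moved single libraries, so chance at the level of the first title number was not tested. With libraries averaged by that number, 1 gene passed on average over ages. Chance was not excluded for the 1 gene of day 14, where 11 of 100 splits gave as many and the highest other gave 24. For counts of 0 all 100 splits gave as many, with highest others of 20, 13 and 25 at days 21, 35 and 70, and of 393, 3, 3 and 98 for the consecutive changes that differed between genotypes. Why single splits gave 393 and 98 genes was not tested.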
